A study of Mus musculus with 3 samples.

How the data were processed

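The series holds 3 libraries of 1 pool of mouse cells: a cDNA library, a library of antibody tags (CD45, CD11b, CD86, CD3e, CD4 and CD25) and a library of hashtags. Per the labels' protocols, brains were perfused, digested with papain, enriched for mononuclear cells on a Percoll density gradient and run on the 10x Genomics 3' assay, version 2, with CITE-seq and cell hashing. Each of the 4 brains carried its own hashtag, and the cells were parted by hashtag after sequencing, per the series' design text.

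The deposited gene values are the natural log of 1 plus the UMI count per 10000 UMIs of the cell, as the authors' table shows: the unlogged values of each cell sum to 10000. Cell Ranger 2.1, Seurat 2.3.4 and the mm10 build are named in the submitters' processing notes, without their roles, and filters on cells and genes are not given in the sources used here. The deposited cell table gives, per cell, the total UMI count, the number of genes, the count of each hashtag and antibody tag (counted with CITE-seq-Count, per the series' design text), and the mitochondrial fraction, all made by the authors. It also gives a hashtag class and a cluster number from 0 to 10. The deposited p-value and q-value of each cell's hashtag assignment were computed by the authors with a method not given in the sources used here, and were not used further. In 100% of cells the deposited class was the hashtag with the highest count. The deposited clusters have numbers and no cell type names.

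UMI counts were recovered from the logged values and the deposited UMI total. Of the nonzero values, 99.8% came out whole within 0.01, the summed counts lay within 10 UMIs of the deposited total, and the number of genes equalled the deposited one in 66.0% of cells, with the deposited number higher by at most 11. Per cell the UMI total ranged from 2495 to 43038 with a median of 9472, and the highest mitochondrial percentage was 24.3%. The median share of hashtag counts from a cell's own hashtag was 78.4%, 74.1%, 89.0% and 94.2% in the brains with hashtags 1, 2, 3 and 4. No cell was removed, and no doublet caller was run. Cells with at least 80% of their hashtag counts from their own hashtag (47.2%, 37.6%, 69.6% and 79.6% of cells) served as the check of mixed droplets.

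The sources used here do not map hashtags to naive and metastatic brains. The tests planned between these conditions (genes in CNS-native myeloid cells and in other cell types, gene lists, cell type shares, surface tags, Cxcl10, and the difference of the effect between myeloid classes) were therefore not run. The shares of microglia-like and marrow-derived-like cells are given with an exact binomial (Clopper-Pearson) 95% interval. The main Cxcl10 levels of these classes are given with an exact Poisson 95% interval. Most other values of a brain are given without an interval. For the share of marrow-derived-like cells a count of 0 is given with the limit that 3 counts would set, and other values of 0 without it. The brain is the replicate.

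Cell types were named from 18 marker lists fixed before the data were examined. Clusters 3 and 6 were taken as immune cells: 96.7% of their 627 cells had a CD45 tag count of at least 300, against 7.55% of other cells. These cells were clustered again on 92 marker genes seen in at least 10 cells, with 15 principal components, 15 neighbours and the Leiden algorithm at resolution 1. Clusterings on the marker genes and on variable genes at resolutions 0.5 and 1 had been looked at first, and resolutions 0.5 and 1.5 were run beside it. Resolution 1 was chosen after their leading genes and the cell numbers per brain had been seen. Clusterings on variable genes parted cells by brain and by interferon genes and were not used. A subcluster led by Ttr and Enpp2 and a subcluster led by Spp1, Pf4 and Apoe were left unnamed, also after seeing them, because their leading genes went against the name that their marker count gave.

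For CNS-native-like against marrow-derived-like cells, values per 10000 were averaged over the cells of a brain and class, with at least 20 cells each, and log2(mean + 0.1) was tested with limma 3.58.1 with an intensity trend and the brain as a block, over genes seen in at least 5% of cells. Counts that passed are at a Benjamini-Hochberg adjusted p of 0.05. The 92 marker genes were left out, since they had made the classes. The brain block pairs the classes because both came from the same animal. The estimated prior degrees of freedom were infinite, in limma and in edgeR, so each gene's p-value rests on the spread of all genes at its level. The SE printed for a gene comes from the same pooled limma spread, not from that gene's own brains. Of 14 gene lists fixed before the data were examined, each was tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The preset test takes its degrees of freedom from the number of genes, and the other tests from the 1 residual degree of freedom of the brains. The lists had been planned for the contrast between conditions, and their use in this comparison was decided after seeing the data.

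The genes named were fixed by a rule: the 10 largest changes in each direction among genes past the threshold whose classes do not overlap between brains, up to 4 members of each list with the smallest p, and Cxcl9, Cxcl10, Cd274, Vsir, Cd86, P2ry12 and Tmem119. That rule gave 73 genes, of which 43 passed the threshold, and not all of the others are described. Of the 20 genes with the largest changes, 1 is not reported here. Further list members that passed were named to complete a count after their values were seen, and the genes of the closing section lie outside the rule. Counts were also simulated for the 6654 genes of this comparison, with 200 changed and a dispersion of 0.05. On these limma recovered 6% of the 2-fold and 36% of the 4-fold changes with 1 false call, and edgeR 4% and 34%. Every simulated gene had the same dispersion and the same mean share of UMIs in both brains. The false call therefore says nothing on the number of false calls in the data.

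Settings varied as fixed before the data were examined were edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on summed recovered counts, size factors by median of ratios, pseudocounts of 0.01 and 1, no filter on low genes or a filter at 20% of cells, a minimum of 10 or 50 cells, summed counts, cells thinned to 2495 UMIs, the fit without the brain block and each brain left out. Chosen after seeing the data were resolutions 0.5 and 1.5, own hashtag of at least 80% and a robust variance estimate. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and leidenalg 0.10.2, and R 4.3.3, were used.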

Results

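The experiment used CITE-seq, a method in which single cells are stained with antibodies that carry sequence tags, so that surface proteins and mRNA are counted in the same droplet. The series compared naive mouse brains with brains bearing metastases of E0771, a mouse mammary carcinoma line, and its title places Cxcl10 from CNS-native myeloid cells at the centre of the question. Tumor cells had been injected into the carotid artery about 2 weeks before collection, and the mice were female C57BL/6 animals aged 2 to 3 months. Cells from 4 brains were stained with 6 antibodies and with a different hashtag antibody per brain, then loaded as one pool. The sources used here do not state which hashtags marked naive and which marked metastatic brains. Each brain is therefore named by its hashtag, its values are given separately, and no naive brain was compared with a metastatic one.

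The deposited table held 4668 cells and 17551 genes. The hashtag 1 brain contributed 844 cells and 4623688 UMIs (unique molecular identifiers, each standing for 1 captured mRNA), and the hashtag 2 brain 410 cells and 2529485 UMIs. The hashtag 3 brain contributed 1385 cells and 17094233 UMIs, and the hashtag 4 brain 2029 cells and 26196431 UMIs. The median depth per cell was 4370.5, 5599.5, 12450 and 12806 UMIs in the brains with hashtags 1, 2, 3 and 4. There was 1 library set for the pool, so intervals on single values below cover counting error only.

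Beside immune cells, the pool held cells of the choroid plexus and of blood vessels. The 880 cells of deposited cluster 1 were choroid plexus-like, with Ttr, the thyroid hormone carrier of the choroid plexus, at 3017 per 10000 UMIs, and with Kl and Folr1. The 295 cells of cluster 4 were endothelial-like, with the tight junction gene Cldn5 at 16.6 per 10000 UMIs, Ly6c1 and Flt1. The 162 cells of cluster 9 were smooth muscle-like and carried the contractile gene Acta2 at 10.9 per 10000 UMIs. Rhox5 was among the leading genes of clusters 0, 2 and 7. The keratin gene Krt8 was at 2.88, 2.92 and 3.14 per 10000 UMIs in these clusters, and at 2.45, 2.23, 1.92 and 1.69 in clusters 9, 10, 5 and 8. Epcam and Krt19 were near 0 in these cells, and the clusters were left unnamed because fewer than 3 of the fixed mammary carcinoma markers marked them.

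The composition of the 4 brains was uneven. Clusters 0, 2 and 7 together made up 11.1%, 10.7%, 56.7% and 61.8% of the cells of the brains with hashtags 1, 2, 3 and 4. Choroid plexus-like cells made up 34.5%, 50.2%, 13.1% and 9.96% in the same order, and endothelial-like cells 8.53%, 13.7%, 5.85% and 4.24%. The CD45-tagged clusters 3 and 6, which hold the immune cells, made up 22.7%, 10.5%, 13.1% and 10.4%. Density gradient enrichment and the efficiency of hashtag staining can set such shares, and no share was compared between groups.

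By marker genes, cells like microglia, marrow-derived monocytes or macrophages, neutrophils and lymphocytes were all found among the 627 immune cells. The 90 microglia-like cells were led by Tmem119, Cx3cr1, Fcrls and P2ry12, genes of resident brain macrophages. The B cell marker Igkc was also among their leading genes, so RNA of B cells was not excluded as its source. Its level in each brain is given in the closing section. The 111 marrow-derived monocyte or macrophage-like cells were led by Ms4a4c, Saa3, Clec4a3 and Tgfbi, and the interferon-induced genes Ifit1, Isg15, Rsad2 and Irf7 were also among their leading genes. Neutrophil-like cells numbered 114, T cell-like cells 67, B cell-like cells 33 and NK cell-like cells 22. An unnamed subcluster of 81 cells was led by the granule genes Ctsg, Mpo, Elane and Prtn3. Another of 69 cells was led by Spp1, Pf4, Apoe and Gpnmb. The median CD3e tag count was 38 in T cell-like cells and 5 in microglia-like cells. The CD11b tag did not part myeloid from lymphoid RNA classes in every brain. Its median was 5129.5 in microglia-like, 6109 in marrow-derived-like, 2564 in T cell-like, 3616.5 in NK cell-like and 2036 in B cell-like cells. In the hashtag 1 brain T cell-like cells stood at 6362 (3 cells), against 2676 in microglia-like cells. In the hashtag 2 brain NK cell-like cells stood at 6282 (3 cells) and B cell-like cells at 6210.5 (2 cells), against 3905. In the hashtag 4 brain B cell-like cells stood at 5322 (10 cells), against 5314.5. All other lymphoid medians lay below that of microglia-like cells of the same brain.

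Microglia-like cells were 6.25% of immune cells in the hashtag 1 brain (exact binomial 95% interval 3.27 to 10.7%), 51.2% in the hashtag 2 brain (35.5 to 66.7%), 14.4% in the hashtag 3 brain (9.60 to 20.3%) and 14.2% in the hashtag 4 brain (9.80 to 19.7%). Marrow-derived-like cells were 3.13% of immune cells in the hashtag 1 brain (1.16 to 6.68%), 28.7% in the hashtag 3 brain (22.3 to 35.9%) and 25.1% in the hashtag 4 brain (19.4 to 31.5%). These numbers depended on the cluster resolution, which was chosen after the cell numbers per brain had been seen. At resolution 0.5 there were 14, 25, 63 and 73 microglia-like cells among the 192, 43, 181 and 211 immune cells of the brains with hashtags 1, 2, 3 and 4, with 5, 1, 51 and 54 marrow-derived-like cells. At resolution 1.5 there were 7, 19, 5 and 10 microglia-like cells and no marrow-derived-like class. The microglia-like class there was led by the immunoglobulin gene Igkc. A border macrophage-like class at that resolution held 0, 0, 17 and 17 cells. Pf4, Ms4a7, Ms4a4c, Tgfbi, Slc7a11 and Cfb were among its leading genes. An unnamed subcluster led by Ms4a4c and Saa3 held 7, 0, 29 and 32 cells. Whether the marrow-derived-like class of resolution 1 held border macrophages was not tested. At resolution 1, in the hashtag 2 brain 0 of 43 immune cells were marrow-derived-like, which allows a share of up to 6.98%. Neutrophil-like cells were 43.2%, 9.30%, 6.63% and 7.11% of immune cells in the brains with hashtags 1, 2, 3 and 4, and T cell-like cells 1.56%, 11.6%, 14.9% and 15.2%. The mean CD86 tag count of microglia-like cells was 137.75 ± 70.0 (SD between cells, 12 cells) in the hashtag 1 brain, 223 ± 113 (22 cells) in the hashtag 2 brain, 214.5 ± 248 (26 cells) in the hashtag 3 brain and 302.7 ± 233 (30 cells) in the hashtag 4 brain. The medians were 118, 224.5, 95 and 251.5 in the same order, so that the hashtag 3 brain had the lowest median.

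Cxcl10 encodes an interferon-induced chemokine that attracts T cells and NK cells through the receptor Cxcr3. In microglia-like cells it stood at 0.885 per 10000 UMIs in the hashtag 1 brain (exact Poisson 95% interval 0.241 to 2.27, 12 cells) and 1.07 in the hashtag 2 brain (0.514 to 1.97, 22 cells). It stood at 2.07 in the hashtag 3 brain (1.29 to 3.13, 26 cells) and at 4.12 in the hashtag 4 brain (3.11 to 5.35, 30 cells). The hashtag 1 brain lay under the planned minimum of 20 microglia-like cells. These Cxcl10 levels depended on which cells were counted, in 2 settings chosen after the data were seen. At cluster resolution 0.5 they were 1.25, 0.954, 0.993 and 2.33 in the brains with hashtags 1, 2, 3 and 4, and among cells with at least 80% own hashtag they were 0, 1.87, 1.61 and 5.99 (6, 10, 21 and 20 cells). The class at resolution 0.5 was led by Spp1 and held 14, 25, 63 and 73 cells, with no separate subcluster led by Spp1 and Pf4. It was thus another mix of cells. A Cxcl10 UMI was seen in 25.0%, 22.7%, 30.8% and 36.7% of microglia-like cells in the brains with hashtags 1, 2, 3 and 4, and in 16.7%, 22.7%, 26.9% and 33.3% once each cell was thinned to 2495 UMIs. Choroid plexus-like cells, taken as the background of free RNA, had a Cxcl10 UMI in 3.09%, 3.40%, 4.97% and 4.46% of cells, and thinned in 0.344%, 0.971%, 1.10% and 1.98%. The median depths behind the unthinned shares were 3983.5, 3359.5, 3495 and 4356 UMIs in microglia-like cells and 6100, 7265.5, 8795 and 7847.5 UMIs in choroid plexus-like cells. Cxcl10 was also found in marrow-derived-like cells, at 1.23 per 10000 UMIs in the hashtag 3 brain (0.805 to 1.81) and 5.24 in the hashtag 4 brain (4.30 to 6.32).

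**Figure D1:**
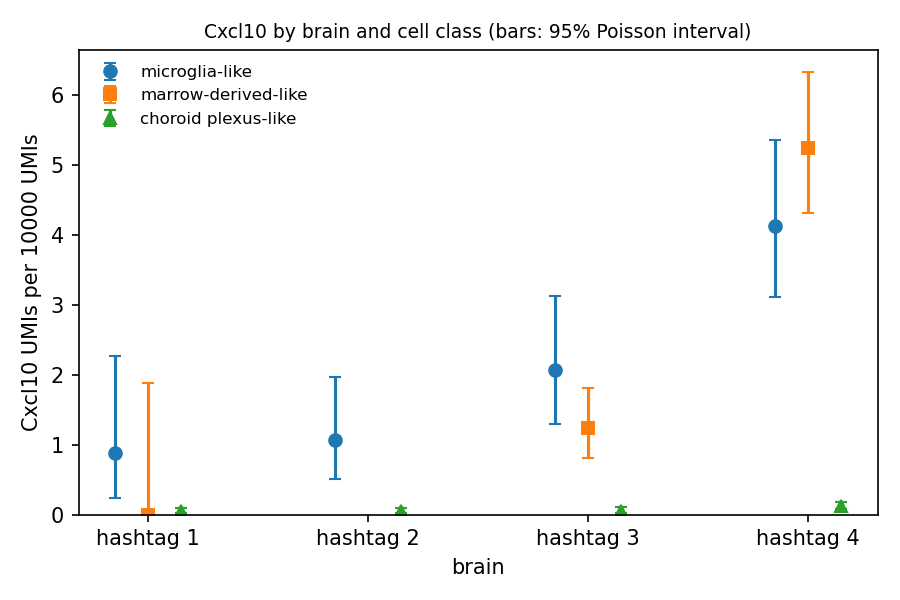
Cxcl10 in UMIs per 10000 UMIs (vertical axis) for each of the 4 brains (horizontal axis), in microglia-like, marrow-derived-like and choroid plexus-like cells; points are sums over the cells of a class and bars are exact Poisson 95% intervals, which cover counting error only. Microglia-like cells lie between 0.885 and 4.12 per 10000 UMIs, and choroid plexus-like cells between 0.0469 and 0.121.

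Cxcl9, a related interferon-induced chemokine, was at 0, 0.107, 0.0939 and 0.809 per 10000 UMIs in microglia-like cells of the brains with hashtags 1, 2, 3 and 4. Cd274, which encodes the checkpoint ligand PD-L1, was at 0.221, 0, 0.376 and 0.294, values that rest on at most 4 UMIs per brain. Vsir, which encodes the checkpoint protein VISTA, was at 3.98, 4.83, 2.25 and 2.65. The co-stimulatory gene Cd86 was at 0.442, 1.502, 1.03 and 1.40. P2ry12, a purinergic receptor of resting microglia, was at 5.09, 5.58, 1.502 and 2.72, and Tmem119 at 6.86, 6.86, 2.16 and 4.56. In the larger class at cluster resolution 0.5, which was led by Spp1, P2ry12 was at 3.75, 5.06, 1.03 and 1.40 and Tmem119 at 5.35, 5.91, 1.80 and 3.05. P2ry12 and Tmem119 were among the markers used to define the class.

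The second comparison set CNS-native-like against marrow-derived-like myeloid cells of the same brain, and so needed no knowledge of the condition of a brain. In microglia-like cells 10 of 17 immediate early genes and 5 of 10 genes of homeostatic microglia outside the marker panel were higher, and 10 of 24 genes of the interferon response and 4 of 7 of MHC class II presentation were lower. Members of all but the last of these lists were among the leading genes of the classes, which had been seen beforehand. The lists passed only in a test that counts genes, not brains, as replicates (limma's camera at a preset correlation). With an estimated correlation the adjusted p was 0.355 for each, but that test has 1 residual degree of freedom, with which a list can hardly pass. The median of the MHC class II list was -1.67 in the hashtag 3 brain and -0.09 in the hashtag 4 brain. The SE values below come from the spread of all genes pooled and do not measure how far the brains lie apart. Cst3, which encodes the protease inhibitor cystatin C, was higher by 1.26 in log2 (SE 0.08; 0.98 in the hashtag 3 brain and 1.55 in the hashtag 4 brain), and the fractalkine receptor gene Cx3cr1 by 1.56 (SE 0.22; 1.62 and 1.51). The interferon-induced genes Isg15 and Ifitm3 had log2 differences of -1.44 (SE 0.19; -1.90 and -0.98) and -1.03 (SE 0.11; -1.10 and -0.97). Cd74, the invariant chain of MHC class II, had a log2 difference of -1.02 (SE 0.10), made up of -1.73 in the hashtag 3 brain and -0.30 in the hashtag 4 brain. Cxcl10 differed by -0.05 (SE 0.26; limma adjusted p = 0.981), with opposite signs in the hashtag 3 brain (0.34) and the hashtag 4 brain (-0.44), and the difference was 0.18 when counts were summed over cells.

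Only the hashtag 3 brain (26 microglia-like and 52 marrow-derived-like cells) and the hashtag 4 brain (30 and 53 cells) reached the planned minimum of 20 cells of both classes. Differences are microglia-like minus marrow-derived-like on the scale log2(mean value per 10000 + 0.1), which understates changes of low genes, and n was 2 brains. Of 6654 genes tested with limma and the brain as a block, 139 passed an adjusted p of 0.05, 65 higher and 74 lower in microglia-like cells. Scaling the profiles by median-of-ratios size factors gave 51 higher and 93 lower. Both brains showed the same sign for 137 of the 139 genes and the classes did not overlap between brains for 115, which follows in part from calling genes on these same 2 brains. With 1 residual degree of freedom the test took its spread, and so each SE, from all genes pooled, not from each gene's own brains. For 33 of the 139 genes the brains differed by more than 1 in log2. DESeq2 on the recovered counts called 12 of these genes, and the fit without the brain block called 4.

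Among the 10 largest increases that passed the test without overlap were Zfhx3, a transcription factor gene, at 1.74 (SE 0.34; limma adjusted p = 4.99e-05), and the membrane protein gene Itm2c at 1.66 (SE 0.30; limma adjusted p = 1.11e-05). Gatm, the first enzyme of creatine synthesis, was higher by 1.82 (SE 0.43), on at most 18 UMIs per brain in either class. The glucose transporter gene Slc2a1 was higher by 1.75 (SE 0.49), made up of 2.67 in the hashtag 3 brain and 0.83 in the hashtag 4 brain. It rested on 17 UMIs in microglia-like against 5 in marrow-derived-like cells of the hashtag 3 brain, and on 7 against 5 in the hashtag 4 brain. Further increases were Ppp1r10 (2.08), Ccng2 (1.94), Arrdc3 (1.88) and Crybb1 (1.81), each resting on at most 17 UMIs per brain in either class. Xcl1 (2.21) was also a leading gene of T cell-like and NK cell-like cells and rested on 2 UMIs in microglia-like cells of the hashtag 3 brain and 15 in those of the hashtag 4 brain, so RNA of lymphocytes was not excluded as its source. Among the 10 largest decreases, Clec4a3, a C-type lectin gene, was at -1.72 (SE 0.30; limma adjusted p = 2.35e-06), and the cystine transporter gene Slc7a11 at -1.72 (SE 0.37; limma adjusted p = 0.00053). Ifit1 was at -1.65 and Ifit3 at -2.04, the latter with -3.52 in the hashtag 3 brain and -0.55 in the hashtag 4 brain. Zfhx3 was among the leading genes of the microglia-like class, and Clec4a3 and Ifit1 among those of the marrow-derived-like class. These genes had been seen beforehand, so their p-values are no independent evidence. The complement gene Cfb (-2.06), Gpr141 (-1.91), Cd69 (-1.90), Plekhf2 (-1.90), Psmc6 (-1.86) and Eif3c (-1.83) completed the decreases, on at most 26 UMIs per brain in either class. Slc7a11 and Cfb were also leading genes of the border macrophage-like class at resolution 1.5. In edgeR Gpr141 (adjusted p = 0.0637), Cd69 (0.102), Plekhf2 (0.103) and Eif3c (0.207) did not pass.

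**Figure D2:**
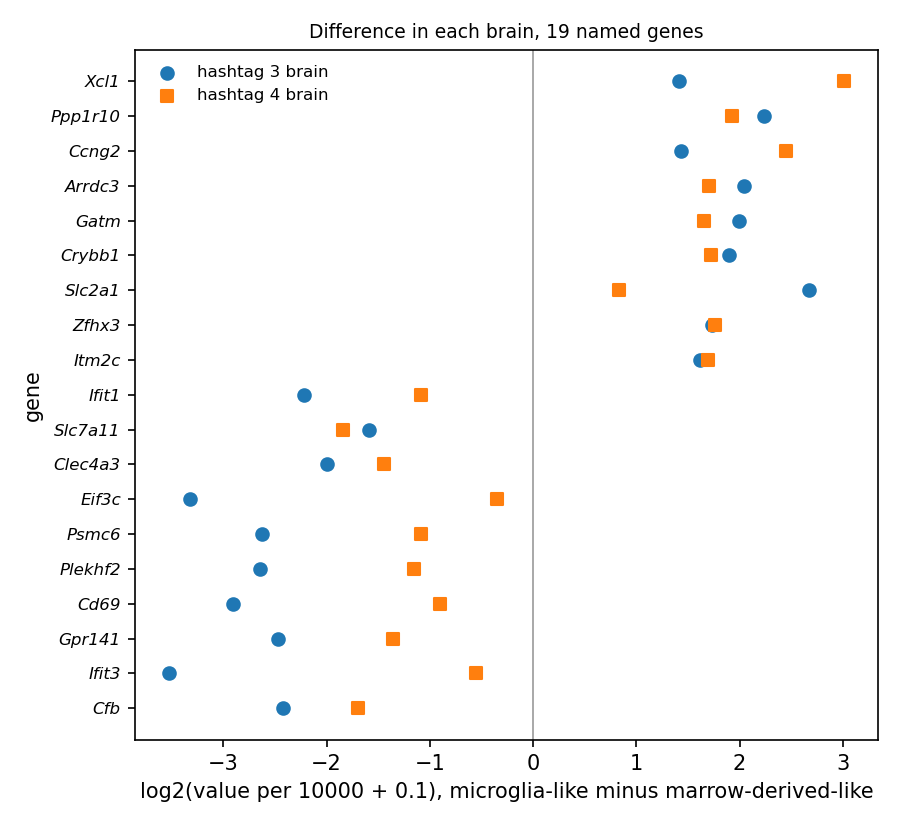
Difference between microglia-like and marrow-derived-like cells in log2(value per 10000 + 0.1) (horizontal axis) for 19 of the 20 genes with the largest changes that passed the test (vertical axis), drawn separately for the hashtag 3 brain (circles) and the hashtag 4 brain (squares). All 19 genes have the same sign in both brains, as their selection without overlap requires, and Ifit3 and Eif3c lie furthest apart, at -3.52 and -0.55 and at -3.32 and -0.35.

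All genes of the homeostatic microglia list that moved rose. Of the 10 measured members outside the marker panel, 5 rose and 0 fell over all genes tested, and 7 rose when adjusted over the list alone. Beside Cst3 and Cx3cr1, the growth factor receptor gene Csf1r rose by 1.07 (SE 0.23), the selectin ligand gene Selplg by 1.05 (SE 0.22) and Jun by 1.302 (SE 0.17). The camera adjusted p from limma was 8.3e-27 with a preset correlation of 0.01, and the adjusted p = 0.355 with an estimated correlation. Because the classes were made from microglia and monocyte markers, genes that vary with those markers differ in part by construction.

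Immediate early genes, which are induced within minutes of stimulation and also by tissue dissociation, rose in 10 of 17 members with 0 falling (12 when adjusted over the list alone). Rhob rose by 1.503 (SE 0.21; 1.44 and 1.57 in the brains with hashtags 3 and 4), Egr1 by 1.29 (SE 0.19; 1.15 and 1.43), Btg2 by 1.18 (SE 0.21; 0.69 and 1.67) and Atf3 by 1.02 (SE 0.25). The camera adjusted p from limma was 2.8e-23, and the adjusted p = 0.355 with an estimated correlation. Jun belongs to this list and to the homeostatic list. Jun and Rhob were among the leading genes of the microglia-like class, seen before the list was used, so this rise was in part known beforehand.

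Interferon response genes fell in 10 of 24 members with 0 rising (18 fell when adjusted over the list alone). Beside Isg15, Ifitm3, Ifit1 and Ifit3, the members that fell were Rsad2, which blocks virus budding, at -1.35 (SE 0.29), Gbp2 at -1.59 (SE 0.38), Zbp1 at -1.24 (SE 0.31), Xaf1 at -1.24 (SE 0.36), Ifi204 at -0.98 (SE 0.30) and Ifi27l2a at -0.69 (SE 0.14). The camera adjusted p from limma was 5.5e-25, and the adjusted p = 0.355 with an estimated correlation. Ifit1, Isg15, Zbp1 and Rsad2 were among the leading genes of the marrow-derived-like class, which had been seen before the resolution was chosen. A fall of this list was thus in part known beforehand and is no independent evidence. MHC class II presentation genes fell in 4 of 7 members: Cd74, H2-Ab1 (-1.08, SE 0.14), H2-Eb1 (-1.08, SE 0.18) and H2-Aa (-0.995, SE 0.16). When adjusted over the list alone 4 fell and 1 rose. These decreases lay mostly in the hashtag 3 brain, where H2-Ab1, H2-Eb1 and H2-Aa differed by -1.90, -2.16 and -1.67, against -0.25, -0.00 and -0.32 in the hashtag 4 brain. The camera adjusted p for this list was 3.7e-13, and the adjusted p = 0.355 with an estimated correlation. MHC class I genes had a camera adjusted p of 1.08e-05 in the negative direction (0.355 as the adjusted p with an estimated correlation) although 0 of 16 members passed over all genes and 2 fell when adjusted over the list alone. Its members with the smallest p were H2-D1 (-0.40, SE 0.13; limma adjusted p = 0.0698) and the immunoproteasome gene Psmb8 (-0.69, SE 0.22; limma adjusted p = 0.074).

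Genes of disease-associated microglia went both ways. Of 18 members 5 rose, with Trem2 (1.14, SE 0.22), Cd9 (0.998, SE 0.21), Spp1 (0.88, SE 0.16), Ctsd (0.76, SE 0.15) and Apoe (0.46, SE 0.08), and 3 fell, with Lilrb4a (-0.92, SE 0.27), Fabp5 (-0.87, SE 0.24) and Lgals3 (-0.63, SE 0.13). When adjusted over the list alone 6 rose and 4 fell. The camera adjusted p from limma was 0.172, with a positive direction while the list's median log2 difference was -0.12 and its mean 0.04. The 69 cells of the subcluster led by Spp1, Pf4, Apoe and Gpnmb were in neither class, and Spp1, Apoe and Gpnmb belong to this list. They had been left unnamed after being seen, so these counts hold only for microglia-like cells without them. At resolution 0.5 the microglia-like class was itself led by Spp1, and this list was not tested there. Chemokines also went both ways: Ccl3 (1.24, SE 0.17) and Ccl4 (0.99, SE 0.13), which attract monocytes and T cells, rose, and Ccl6 (-0.97, SE 0.20), Ccl9 (-0.93, SE 0.22) and the neutrophil attractant Cxcl2 (-0.60, SE 0.16) fell, among 12 members (3 rose and 3 fell over the list alone; camera adjusted p = 0.973).

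In the remaining 7 lists few members passed. The lysosome and phagocytosis list had 1 of 14 that rose, Lgmn (0.48, SE 0.14; edgeR adjusted p = 0.125), and 1 that fell, the scavenger receptor gene Msr1 (-1.43, SE 0.32; camera adjusted p = 0.195), or 1 and 2 over the list alone. Glycolysis had 1 of 15, Slc2a1, the same count over the list alone, with a list median of -0.09 against a mean of 0.08 and a negative test direction (camera adjusted p = 0.973). The T and NK effector list had 1 of 7, Cd69, which did not pass in edgeR (2 fell over the list alone; camera adjusted p = 0.973), with a median of 0.23, a mean of -0.15 and a negative test direction. The inflammatory cytokine list had 0 of 10 over all genes, 4 that rose and 2 that fell over the list alone (camera adjusted p = 0.0625). There, Il1a was at 1.35 (SE 0.42; limma adjusted p = 0.0598), Tnf at 0.90 (SE 0.30; limma adjusted p = 0.0991), Tnfaip3 at 0.97 (SE 0.32) and Nfkbiz at 0.73 (SE 0.24). The checkpoint list (0 of 10; camera adjusted p = 0.515), the co-stimulation list (0 of 6; camera adjusted p = 0.973) and the cell cycle list (0 of 10; camera adjusted p = 0.696) had 0 members past the threshold over all genes and over the list alone. Their members with the smallest p were Lag3 (0.96, SE 0.42; limma adjusted p = 0.327), Icam1 (0.88, SE 0.39; limma adjusted p = 0.334; -0.26 and 2.02 in the brains with hashtags 3 and 4) and Pcna (0.82, SE 0.41; limma adjusted p = 0.452). Vsir was at 0.61 (SE 0.30; limma adjusted p = 0.434), Cd274 at -0.87 (SE 0.49; limma adjusted p = 0.546), Cxcl9 at -0.90 (SE 0.45; limma adjusted p = 0.441) and Cd86 at -0.09 (SE 0.34; limma adjusted p = 0.973; 0.17 when cells were thinned to equal UMIs and 0.27 among cells with at least 80% own hashtag).

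Markers of other cells were present in both classes. Ttr, of choroid plexus cells, was at 130.5 per 10000 UMIs in microglia-like and 155 in marrow-derived-like cells of the hashtag 3 brain, and at 123 and 137 in the hashtag 4 brain. S100a8, of neutrophils, was at 4.51 and 5.92 in the hashtag 3 brain and at 18.3 and 6.15 in the hashtag 4 brain, in the same order. Among cells with at least 80% of their hashtag counts from their own hashtag, a check chosen after the data were seen, 44 genes passed, 19 higher and 25 lower, and 42 of them were among the 139.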

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

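All explanation tests in this part were chosen after the results were seen. For each of 37 shares and levels, the highest or lowest brain's gap to the nearest other brain was set against the whole range of the 4 brains, and 3 values stood apart by Dixon's test at the 95% level. Chance alone gives about 1 in 20, and here the 4 brains come from 2 conditions that were not mapped, so a value can also stand apart through its condition.

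Cluster 6, with the neutrophil granule genes Camp, Ngp and S100a8, made up 20.3% of the cells of the hashtag 1 brain, against 0.838 to 2.20% in the other 3 brains. The neutrophil-like class, drawn from clusters 3 and 6, made up 43.2% of immune cells there, against 6.63 to 9.30%. In microglia-like cells of the hashtag 4 brain Cxcl9 stood at 0.809 per 10000 UMIs (exact Poisson 95% interval 0.404 to 1.45, from 11 UMIs), against 0 to 0.107 in the other 3 brains.

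Wrong hashtag calls would place cluster 6 cells of other brains under hashtag 1, yet 80.1% of the cluster 6 cells of this brain (73.3 to 85.8%) had at least 80% of their hashtag counts from hashtag 1, against 38.8% of its other cells (35.1 to 42.6%), which argues against this explanation. Bone marrow cells carried along at dissection would bring B cell precursors. A UMI of the precursor genes Vpreb1, Vpreb3 or Igll1 was seen in 14 of 16 B cell-like cells of this brain (87.5%, 61.7 to 98.4%), against 50 of 291 of its choroid plexus-like cells (17.2%), but these genes were among the leading genes of the B cell-like subcluster and had been seen before the test was made, so the value decides nothing. In the brains with hashtags 2, 3 and 4 the numbers were 0 of 2, 2 of 5 and 2 of 10 cells, and a first form of the test, which pooled them, had been replaced after its result was seen. Bone marrow as a source therefore stays open, and no biological explanation was tested, since the condition of the brain is not given in the sources used here. The unnamed subcluster led by Ctsg, Mpo, Elane and Prtn3 had 54, 2, 13 and 12 cells in the brains with hashtags 1, 2, 3 and 4. Myb and Cdk6 were also among its leading genes. In the hashtag 1 brain its median tag counts were 716.5 for CD45 and 90.5 for CD11b, against 4998 and 5143 in neutrophil-like cells. Whether these cells came from marrow was not tested.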

How the results depend on the processing

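Tests with the gene lists, cluster resolution 0.5, own hashtag of at least 80% and the robust variance estimate were chosen after the results were seen. Against 139 genes called between microglia-like and marrow-derived-like cells, the fit without the replicate block called 4, DESeq2 12, a filter at 20% of cells, which tested 2280 genes, 65, and cells with at least 80% own hashtag, which left 21 and 20 microglia-like cells in the brains with hashtags 3 and 4, 44, of which 42 were among the 139. The cause of these lower counts was not tested. In the other 10 settings, edgeR, size factors, pseudocounts of 0.01 and 1, no low filter, a minimum of 10 cells, summed counts, thinned cells, resolution 0.5 and robust variance, between 99 and 168 genes passed, of which 84 to 139 were among the 139. The minimum of 10 cells left the same brains and so repeated the main fit, and its 139 genes in common are no check. Resolution 0.5 had 86 in common out of 168.

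All 5 list calls by camera at the preset correlation were lost with an estimated correlation (adjusted p = 0.355 in each) and with fry (adjusted p = 0.411 for homeostatic microglia, 0.397 for interferon response, 0.445 for MHC class I, 0.626 for MHC class II and 0.411 for immediate early genes). Both tests take the 1 residual degree of freedom, with which a list can hardly pass (smallest unadjusted p among the 14 lists 0.0543 and 0.0214), so the loss says nothing on the correlation within a list. The preset test counts genes, not brains, as its replicates, and its 5 calls held at a pseudocount of 1 and without genes in 2 lists. The T and NK effector list turned its direction at a pseudocount of 1 (adjusted p = 0.947), with neither direction past the threshold.

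Of the single genes, 8 values turned their sign in the settings with a test, and the cause was not tested. At resolution 0.5 these were Ccl5 (-0.51), Pvr (-0.32), Birc5 (0.28) and Ube2c (0.0355), of which Ccl5 then passed the threshold. With at least 80% own hashtag they were Cd40 (0.0869) and Cd86 (0.27), with thinned cells Cd86 (0.17) and with summed counts Cxcl10 (0.18). Across the settings with a test, 148 values of the named genes lost and 13 gained the threshold, and 840 were unchanged, which for the values with a brain left out means within the standard error. The 840 include the values at a minimum of 10 cells, which repeated the main fit. With either brain left out the other brain's difference is a value with no test, and 90 such values moved by more than the standard error. The main value is the mean of both brains, so both lie equally far from it. The 90 values are therefore 28 genes past the threshold and 17 short of it, each counted once per brain, and not separate checks. Among named genes short of the threshold, 6 turned their sign without the hashtag 3 brain and 3 without the hashtag 4 brain, Cxcl10 among the latter, and 0 of those past it did.

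Of each brain's cell type shares, 63 stayed within their binomial interval and 113 moved beyond it, most of the 113 where only immune cells or only cells above the median UMI count were taken. A share of immune cells has another denominator, and few immune cells lay above the median UMI count. Such moves follow from the cells taken and are no check of the shares. Of the microglia-like levels 9 moved and 103 did not. Of 108 mean tag counts, 41 differed from their median by more than 1.5 times. A minimum of 50 cells left no brain with enough microglia-like cells, and resolution 1.5 gave no marrow-derived-like class, so neither gave a value. The planned contrasts between naive and metastatic brains were not run. Depth limits genes such as Cd274, with at most 4 UMIs per brain in microglia-like cells.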

Other observations

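The tests on Lcn2 in this part were chosen after its level had been seen, and a first form that took Lcn2 and Mt2 together was narrowed to Lcn2 after the results were seen. Lcn2, which encodes the iron-scavenging acute phase protein lipocalin 2, stood at 57.7 per 10000 UMIs in endothelial-like cells of the hashtag 3 brain, and at 2.87, 0.373 and 1.91 in the brains with hashtags 1, 2 and 4. An Lcn2 UMI was found in 71.6% of these cells in the hashtag 3 brain (exact binomial 95% interval 60.5 to 81.1%), and in 33.3% (22.7 to 45.4%), 16.1% (7.62 to 28.3%) and 26.7% (17.8 to 37.4%) in the brains with hashtags 1, 2 and 4. The stress gene Mt2, which encodes a metallothionein, was at 17.6 per 10000 UMIs in the same cells of the hashtag 3 brain and at 7.10, 4.25 and 4.27 in those with hashtags 1, 2 and 4. In the unnamed cluster 8 Mt2 was at 2.59, 6.96, 39.7 and 3.12 in the brains with hashtags 1, 2, 3 and 4.

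Neutrophil RNA or doublets would bring S100a9 with Lcn2, and the endothelial-like cells of the hashtag 3 brain held 0.0178 S100a9 UMIs per Lcn2 UMI, against 11.5 in its neutrophil-like cells, which argues against that source. Free RNA would reach all cells alike, and choroid plexus-like cells of this brain held 0.302 Lcn2 UMIs per 10000. The 5 cells with most Lcn2 held 27.3% of its UMIs in this brain, so the level does not rest on a few cells. The Lcn2 level may thus belong to the endothelial-like cells of this brain, as a hypothesis from a single brain, and no biological explanation was tested.

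Summed over each fixed list, microglia-like cells held homeostatic genes, marker genes included, at 446, 418.5, 167 and 252 UMIs per 10000 in the brains with hashtags 1, 2, 3 and 4. Disease-associated genes were at 133, 189, 242 and 274, and interferon response genes at 42.0, 31.3, 53.0 and 80.9, in the same order. MHC class II genes were at 58.6, 141, 77.6 and 163, and immediate early genes at 207, 246, 171 and 164. Immune checkpoint genes were at 14.4, 13.3, 11.2 and 11.3. The immunoglobulin gene Igkc, which microglia do not make, was at 2.43, 209, 0.282 and 1.25 per 10000 UMIs in these cells, with a UMI in 31.8% of microglia-like cells of the hashtag 2 brain. Cxcl10 was at 0.266 per 10000 UMIs in T cell-like cells of the hashtag 3 brain (3 UMIs in 27 cells) and at 2.82 in those of the hashtag 4 brain (34 UMIs in 32 cells).

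Over all cells, the shares of clusters 0, 2 and 7 fell into separate sets, with 11.1% and 10.7% in the brains with hashtags 1 and 2 and 56.7% and 61.8% in those with hashtags 3 and 4, and no condition was inferred from them. They depended on the cells taken: 51.3%, 24.4%, 86.1% and 85.6% in the brains with hashtags 1, 2, 3 and 4 among cells above the median UMI count, and 8.04%, 5.19%, 62.3% and 67.3% among cells with at least 80% own hashtag. A first test of explanations for these cells compared the brains in groups taken from these same values, and was dropped after it had been run. At least 80% of hashtag counts came from the own hashtag in 34.0%, 18.2%, 76.6% and 86.8% of these cells in the brains with hashtags 1, 2, 3 and 4, and in 48.8%, 39.9%, 60.5% and 68.0% of the other cells of each brain. Xist, transcribed from the inactive X chromosome, was at 3.52, 4.80, 0.440 and 0.392 per 10000 UMIs in clusters 0, 2 and 7, and at 8.94, 9.23, 5.87 and 5.32 in choroid plexus-like cells. Ttr, the choroid plexus gene, was at 819, 1135, 127 and 123 in clusters 0, 2 and 7.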
